A study of Mus musculus with 6 samples.

How the data were processed

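RNA was sequenced from 6 libraries of mouse primary cortical neurons, 3 transduced with a control short hairpin RNA and 3 with one directed against Opa1. Per the labels' protocols, libraries were made with a stranded mRNA kit that selects polyadenylated RNA. The deposited table holds raw read counts per gene, made by the authors with featureCounts 1.6.0 in paired mode on Ensembl release 99 gene models of GRCm38, per the file headers. The header's command gives no strand option, so reads from a gene and an overlapping antisense gene cannot be told apart, and it gives no option for reads with several matches or for reads that overlap several genes. The submitters' processing notes name HISAT2, DESeq2 and the build mm10 without versions. The authors also deposited a table of their comparison with a log2 fold change, standard error and p-value per gene, a score that is the fold change divided by its error, and counts divided by 1 size factor per library, a normalised signal. Replicates were not pooled.

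The count table lists 55471 gene identifiers, of which 55144 were paired with a symbol through a reference table and 32943 had at least 1 count. No row lacked a gene identifier, and 0 columns of values lacked a sample. Library totals ran from 24676709 to 32961580 counts. Libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom between 6.81 and 34.5 over genes, so none was counted as a repeat of another. Where each culture came from is given only as biological replicates, and p-values measure the spread between these libraries. Intervals on shares of genes cover counting error only.

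Groups and replicate numbers came from the sample labels. The main test was edgeR 4.0.16 (R 4.3.3) with TMM scaling, the default low-count filter, robust dispersion and the quasi-likelihood test, with shOpa1 against shControl as the only term and Benjamini-Hochberg adjustment at 0.05. Standard errors were taken as the log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. The replicate numbers are shared by both groups, so it was checked whether they pair the libraries. Deviations from the group means correlated at 0.519, 0.537 and 0.666 for libraries with the same number, and every library correlated best with its own number, so the numbers were taken as pairs. The labels give no batch, but a second one is inferred from the data: both libraries numbered 3 lay at -38.3 and -36.9 on the second principal component and the other 4 between 17.4 and 20.4. In the labels' sample codes these libraries also stand apart from the other 4, whose codes run on from each other. The authors' deposited log2 fold changes differed by more than 1e-05 for 0 genes from a DESeq2 1.42.0 fit here with replicate 3 as a second batch, and both call 7935 genes.

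The lists of genes, the rule for named genes, the tests and the alternatives were fixed before the data were examined, except where the text says otherwise. There were 33 lists on stress programs, mitochondria, metabolism, neuronal function and cell types, each named where its result stands. Each list with at least 5 measured members was tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, and beside it with an estimated correlation and with fry, directional and mixed. Named genes were Opa1, the 12 highest and 12 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 50 counts per library, a symbol that is not a predicted gene and no overlap between groups, and up to 4 members of each list with the smallest p, or up to 2 where none passed. Atf4, Slc7a11, Pycr1, Cebpg, Spg7, Mrpl48, Ndufv2, Ndufa3, Perp, Ccng1, Gfap, mt-Co1, mt-Cytb, mt-Rnr1, mt-Rnr2, Mcm3, Mcm4, Mcm6, Mcm7, Cdt1, Chaf1b, Top2a and Cdk1 fall outside the rule and were chosen after their values were seen. Values of some genes the rule would name are not reported here.

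The search of 3' UTRs was added after fold changes had been seen, and what each outcome would mean was written down before it was run. The longest 3' UTR among each tested gene's protein-coding transcripts (GENCODE mouse release 21, GRCm38) was taken where it had at least 50 bases, which gave 13850 genes without Opa1, 83.6% of those tested. For each of 16220 7-base sequences carried by at least 50 genes, the log2 fold change was regressed on carriage after removing the trend on UTR length and base composition, and the extremes were compared with 100 permutations of the fold changes. Pair differences used log2(CPM + 0.5). Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1 was used.

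The fits, camera and the sequence search were tested on simulated data, and fry was not. With counts drawn from the real means, library sizes and dispersions of the 16562 genes for this comparison, edgeR called 131 of 200 genes changed 2-fold (65.5%) and 11 unchanged genes, edgeR with the replicate block 131 and 19, DESeq2 145 and 45, and limma-voom 130 and 9. These simulated counts held no pair or batch effect, so they do not test what the block does in paired libraries. Each gene was drawn independently of the others, so the simulation could not test the preset correlation of camera. A planted shift of -0.4 on carriers of a sequence was ranked first for 10 of 10 sequences over 13850 genes, and a shift of -0.1 for 8 of 10. Alternatives covered the replicate block, RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2, limma-voom, a fold change of at least 2, and leaving out each library. Alternatives chosen after seeing the data were replicate 3 as a second batch, pairs 1 and 2 alone, leaving out genes with the 3' UTR sequence, and camera with an estimated correlation and the replicate block.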

Results

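Gene expression was measured by RNA sequencing in primary cortical neurons taken from CD1 mouse embryos no older than embryonic day 15. The cultures were kept with 2 uM Ara-C, a drug that stops dividing cells. They were transduced on day 6 with lentivirus carrying a control short hairpin RNA (shControl) or one directed against Opa1 (shOpa1), and RNA was taken on day 11. Opa1 encodes a GTPase of the inner mitochondrial membrane that fuses inner membranes and shapes cristae. Each group held 3 libraries, numbered 1 to 3 and described as biological replicates. The shControl libraries held 24676709, 28142558 and 28253400 counts and the shOpa1 libraries 29476268, 32961580 and 31577722. The comparison asks which transcripts of cortical neurons change when Opa1 is depleted.

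Opa1 itself fell 22.3-fold, and in all 3 knockdown libraries. Opa1 (ENSMUSG00000038084) lies on chromosome 16 from 29579334 to 29654884 on the plus strand (GRCm38). The shControl libraries held 201.8, 204.6 and 201.9 CPM of its transcript, in counts scaled by library size, and the shOpa1 libraries 10.2, 8.64 and 8.50 CPM. The group means were 203 ± 1.54 and 9.10 ± 0.916 CPM (SD, n = 3). The log2 fold change was -4.48 with a standard error of 0.0876 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.09e-06). It was -4.43 in pairs 1 and 2 and -4.56 in pair 3.

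Other genes moved in both directions. Among the genes with the steepest rise were Nupr1, Trib3 and Eif4ebp1, genes of the integrated stress response, the program driven by the transcription factor ATF4. Their log2 fold changes were 3.49, 2.51 and 2.43. Cth, an enzyme that makes cysteine, rose by 2.74, and Hmox1, which degrades haem, by 2.43. The RNA-binding antiviral factor Zc3hav1 led the list at 3.75, from 0.374 ± 0.0388 to 5.09 ± 1.16 CPM (SD, n = 3). The reductase Cyb5r2 rose by 3.48, the matrix protein Tnxb by 3.38, ceruloplasmin (Cp) by 2.71, Fibin by 2.63, the potassium channel subunit Kcns1 by 2.61 and the complexin Cplx3 by 2.59. After Opa1 the steepest falls belonged to the axon guidance protein Draxin (-2.94), Nacc2 (-2.92), Pgm2l1 (-2.86), Sowahc (-2.59), Adamts2 (-2.57), Srd5a1 (-2.53), Prima1 (-2.45), Hipk2 (-2.44), Amot (-2.38), the gap junction protein Gja1 (-2.37) and Pcyox1 (-2.35). Of these, Pgm2l1 was the most abundant, at 384 ± 21.7 CPM in shControl and 53.04 ± 8.06 CPM in shOpa1 (SD, n = 3).

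In total, 6442 of 16562 tested genes passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 3130 higher and 3312 lower in shOpa1. A fit with the replicate number as a block called 9851 genes, 4770 higher and 5081 lower. At least a 2-fold change was seen for 520 of the higher and 935 of the lower genes without the block, and for 619 and 1044 with it. The 3 shOpa1 and the 3 shControl libraries did not overlap for 51.8% of the tested genes, against 10% by chance if the libraries were exchangeable. Libraries with the same number were alike, so that 10% is only a rough guide. Both libraries numbered 3 stood apart from the other 4 along the second principal component, which held 26.4% of the variance. Pairs 1 and 2 alone called 8496 genes, 4143 higher and 4353 lower, while pair 3 has 1 library per group and allows no test. Across tested genes the pair 3 difference correlated with the mean of pairs 1 and 2 at r = 0.811, genes not being independent replicates. The authors' deposited table lists 7935 genes at an adjusted p under 0.05, 3915 higher and 4020 lower, of which 6136 were also called here and 0 with the opposite sign.

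**Figure D1:**
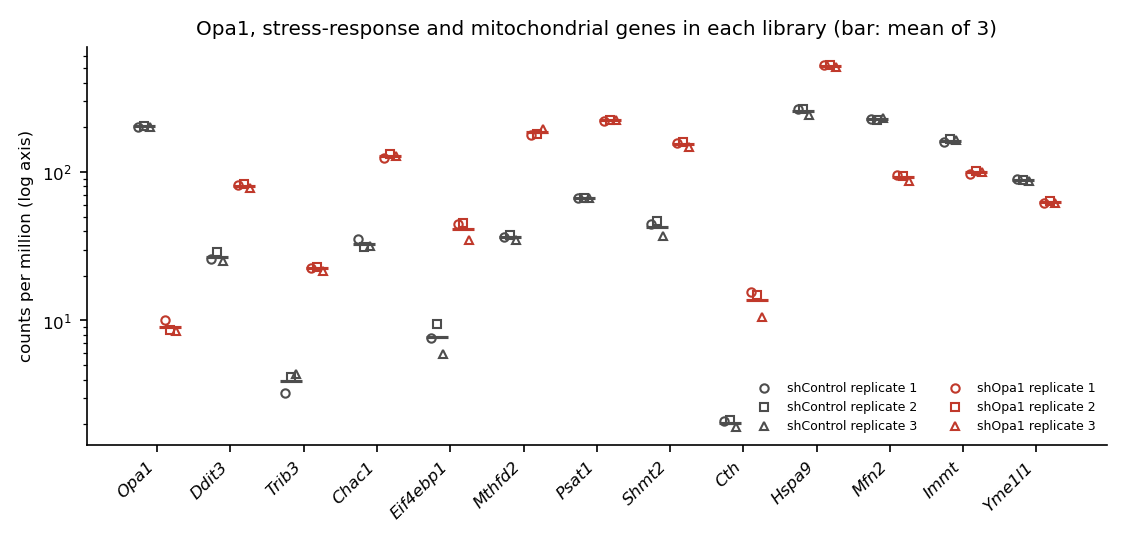
CPM on a log axis for 13 genes; each symbol is 1 library, with circles, squares and triangles for replicates 1, 2 and 3, and each bar is the mean of 3 libraries. Opa1 lies near 203 CPM in shControl and 9.10 CPM in shOpa1, stress-response genes such as Mthfd2 lie higher in every shOpa1 library, and Mfn2, Immt and Yme1l1 lie lower.

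Genes whose 3' untranslated region (UTR) holds the 7-base sequence GAAACTA were lower in shOpa1 as a set. GAAACTA was picked for this shift, as the most extreme toward lower values among 16220 sequences searched on the same fold changes. The sequence was present in the 3' UTR of 1334 of 13850 genes searched, among them Draxin, Nacc2, Pgm2l1, Sowahc, Gja1 and Pcyox1, which make up 6 of the 11 genes with the steepest falls after Opa1. None of the 12 genes with the steepest rises carried it. The median log2 fold change was 0.02 for the 12516 genes without the sequence, -0.40 for the 1165 genes with 1 copy and -0.72 for the 169 genes with 2 or more. Of the carriers, 671 were called lower and 107 higher, against 2341 lower and 2760 higher of the genes without it. It was carried by 36.3% of the 757 searched genes that fell at least 2-fold (95% Wilson interval 32.98 to 39.81%) and by 3.8% of the 399 that rose at least 2-fold (2.29 to 6.11%). Compared with all other searched genes the odds ratio for a fall of at least 2-fold was 6.48 (two-sided Fisher's exact test, p = 1.45e-95). These shares and this p-value do not allow for the choice of the sequence from the same data, and they treat genes as independent. The median difference between carriers and other genes was -0.395, -0.421 and -0.454 in pairs 1, 2 and 3. The sequence occurs once in the Opa1 mRNA, in the coding sequence at bases 1452 to 1458 of transcript Opa1-206, in exon 13 of 29, on chromosome 16 from 29611584 to 29611590 (GRCm38, plus strand). Genes named from here on that carry it are marked as carriers.

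**Figure D2:**
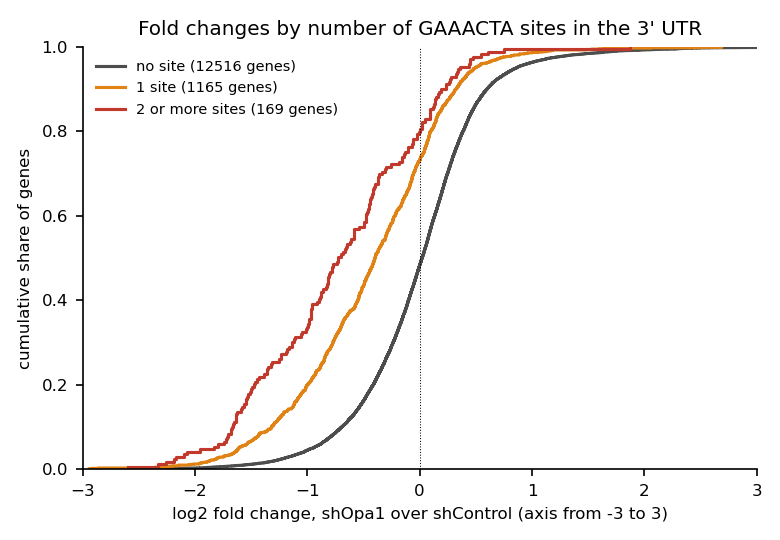
Cumulative share of genes against the log2 fold change of shOpa1 over shControl, drawn from -3 to 3, for genes with 0, 1 or at least 2 copies of GAAACTA in the 3' UTR. The curves of the 1165 genes with 1 copy and the 169 genes with more lie to the left of the curve of the 12516 genes with none, with medians of -0.40, -0.72 and 0.02.

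Of 32 gene lists tested with camera, 13 were called, 8 up and 5 down, none of them with an estimated correlation. Fry asks whether members change at all, where camera compares them with other genes. Fry called 16 by direction, but not the camera-called nuclear OXPHOS, immediate early and cytosolic ribosomal lists (fry adjusted p = 0.267, 0.116 and 0.0923). It also called lists that camera did not. Lower were the presynaptic vesicle cycle (fry adjusted p = 0.00157), neuronal cytoskeleton and identity (0.00167) and calcium handling (0.00291). Higher were NF-kB and inflammatory (0.00761), NRF2 and antioxidant (0.021) and mitochondrial biogenesis and mtDNA maintenance genes (0.0496). Integrated stress response genes rose almost as a block. Of 42 measured ATF4 targets and related genes, 38 were higher and 2, Ddit4 and the carrier Cebpg, were lower, and the counts adjusted over the list alone were also 38 and 2. The median log2 fold change was 1.20, with 1.21 in pairs 1 and 2 and 1.23 in pair 3. Ddit3, which encodes the stress transcription factor CHOP, rose from 26.6 ± 1.95 to 80.7 ± 2.83 CPM, and the glutathione-degrading enzyme Chac1 from 32.7 ± 2.12 to 127.7 ± 3.85 CPM (SD, n = 3). Atf4 rose by 0.93 on the log2 scale, from 327 to 625 CPM. The members that did not pass, Slc7a11 and the carrier Pycr1, had log2 fold changes of -0.05 and -0.05. As a list these genes stood above other genes (camera, limma, adjusted p = 3.04e-17), a call that was lost with a correlation estimated per list (adjusted p = 0.179 with an estimated correlation).

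Several enzymes of serine and one-carbon metabolism rose with them. Mthfd2, the mitochondrial folate dehydrogenase, rose from 36.3 ± 1.31 to 185 ± 9.74 CPM, the serine synthesis enzyme Psat1 from 66.6 ± 0.0207 to 222 ± 2.51 CPM, and the serine hydroxymethyltransferase Shmt2 from 42.7 ± 4.93 to 154 ± 6.81 CPM (SD, n = 3). Aldh1l2 rose by 1.11 on the log2 scale. Of the 18 genes of serine and folate one-carbon metabolism, 12 rose and 1 fell (12 and 1 adjusted over the list alone), with medians of 0.75 in pairs 1 and 2 and 0.60 in pair 3. Lower members numbered 3 in the fit with the replicate block. The list shares 5 genes with the stress-response list. Its camera adjusted p was 0.000301 (adjusted p = 0.179 with an estimated correlation).

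The 13 mRNAs encoded by mitochondrial DNA all fell. Their median log2 fold change was -1.36, with -1.27 in pairs 1 and 2 and -1.40 in pair 3, and 13 of 13 were called, also when adjusted over the list alone. The complex I subunit mRNA mt-Nd1 fell from 5605 ± 1236 to 2232 ± 387 CPM and mt-Nd2 from 3685 ± 718 to 1577 ± 229 CPM (SD, n = 3). The cytochrome oxidase mRNA mt-Co1 fell from 13950 to 5830 CPM and mt-Cytb from 8723 to 3125 CPM. Mitochondrial genes took 4.16, 5.31 and 3.19% of the counts in shControl replicates 1 to 3 and 2.13, 2.38 and 1.59% in shOpa1. mt-Co2 and mt-Atp6 also fell, by 1.34 and 1.22 on the log2 scale, but were counted at only 24.1 and 7.69 CPM in shControl, and levels of mitochondrial genes are uncertain where nuclear copies of mitochondrial DNA share their reads. The camera adjusted p was 8.54e-06 (adjusted p = 0.56 with an estimated correlation). These mRNAs have no annotated 3' UTR and stood outside the search of 3' UTRs, and 0 of the 13 transcripts held GAAACTA at any place.

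**Figure D3:**
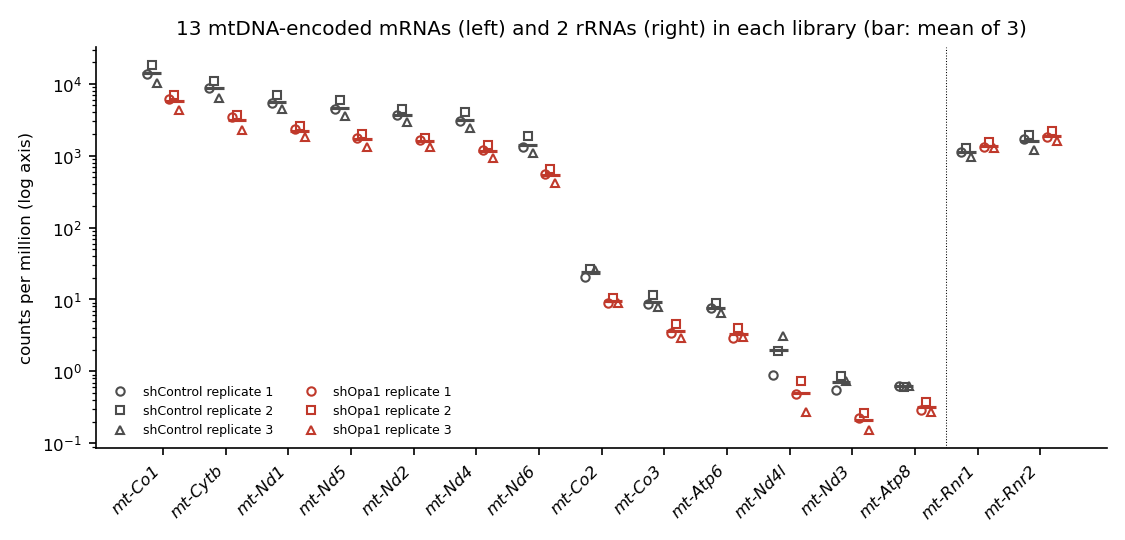
CPM on a log axis for the 13 mRNAs and 2 rRNAs encoded by mitochondrial DNA; each symbol is 1 library and each bar the mean of 3. For every mRNA the mean is lower in shOpa1, as for mt-Nd1 at 5605 against 2232 CPM, while mt-Rnr1 and mt-Rnr2 show log2 fold changes of 0.31 and 0.21 that did not pass the test without the replicate block.

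Nuclear genes for the respiratory chain and the mitochondrial ribosome did not fall with them as lists. Of 75 nuclear OXPHOS subunits, 18 rose and 3 fell (15 and 3 adjusted over the list alone), among them Ndufa10 at a log2 fold change of 0.59, Sdha at 0.45 and Ndufa8 at 0.44. The complex I subunit Ndufs8, a GAAACTA carrier, fell from 55.3 ± 2.62 to 22.3 ± 2.35 CPM (SD, n = 3), and Ndufv2 and Ndufa3 fell by 0.51 and 0.48. With the replicate block 48 rose and 8 fell. The list median was 0.17 (0.16 in pairs 1 and 2, 0.19 in pair 3), with a camera adjusted p of 0.00349 (adjusted p = 0.814 with an estimated correlation). That call was lost without shControl replicate 3 (adjusted p = 0.0855) and without shOpa1 replicate 2 (adjusted p = 0.0543). Fry did not call this list without the block (fry adjusted p = 0.267) but did with it (fry adjusted p = 0.0149). Of 77 mitochondrial ribosomal protein genes 39 rose and 1, Mrpl48, fell (41 and 1 adjusted over the list alone; 53 and 5 with the replicate block), with Mrps14 at 0.90, Mrpl45 at 0.87, Mrps22 at 0.69 and Mrps26 at 0.61. The median was 0.31 (0.29 and 0.30 within pairs 1 and 2 and pair 3; camera adjusted p = 1.75e-06, adjusted p = 0.632 with an estimated correlation). Of 84 cytosolic ribosomal protein genes 27 rose and 3 fell, 42 and 7 with the replicate block and 26 and 3 adjusted over the list alone, and their median was 0.14 (0.12 in pairs 1 and 2, 0.19 in pair 3; camera adjusted p = 0.00385, adjusted p = 0.726 with an estimated correlation). Rps27l rose by 1.00, Rps6 by 0.45 and Rpl6 by 0.32, whereas Rps4x, a carrier, fell by 0.94. All 3 list medians stayed above 0 under each scaling tried. Many ribosomal protein genes have near-identical processed copies, so their counts are uncertain.

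Most chaperones and proteases of the mitochondrial matrix and inner membrane rose. The matrix Hsp70 gene Hspa9 rose from 258 ± 14.8 to 519 ± 7.53 CPM (SD, n = 3) and the import channel gene Timm23 by 0.56 on the log2 scale. The carriers Dnaja3 and Yme1l1, the latter a protease that cuts the Opa1 protein, fell by 0.74 and 0.50, and Spg7 fell by 0.27. Of 18 genes 11 rose and 3 fell (13 and 3 adjusted over the list alone), the median was 0.35 (0.32 in pairs 1 and 2, 0.43 in pair 3), and the camera adjusted p was 0.0136 (adjusted p = 0.69 with an estimated correlation). Genes of mitochondrial fusion, fission and cristae went both ways. The outer-membrane fusion GTPase Mfn2, a carrier, fell from 228 ± 4.11 to 92.1 ± 4.90 CPM and Immt, the core of the cristae junction complex and also a carrier, from 163 ± 3.69 to 99.4 ± 2.10 CPM (SD, n = 3). Mff, a receptor for the fission machinery, rose by 0.46. Of the 24 measured, 6 rose and 7 fell (7 and 8 adjusted over the list alone), 3 of the lower ones being carriers, and the list was not called (camera adjusted p = 0.713; median -0.07, with -0.03 in pairs 1 and 2 and -0.12 in pair 3).

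Other mitochondrial lists moved member by member, and camera without a block or batch term did not call them over all 6 libraries. Fry did call calcium handling lower (fry adjusted p = 0.00291) and biogenesis and mtDNA maintenance higher (fry adjusted p = 0.0496). In the tricarboxylic acid cycle 9 of 20 rose and 3 fell (11 and 3 adjusted over the list alone; 13 and 4 with the replicate block), with Idh3a at 0.64, Sucla2 at 0.47 and Idh2 at 0.44 (camera adjusted p = 0.0706). This list was called without shOpa1 replicate 3 (adjusted p = 0.0125), in pairs 1 and 2 alone (adjusted p = 0.0377) and with replicate 3 as a second batch (adjusted p = 0.0438), but not with an estimated correlation over all 6 libraries (adjusted p = 0.802, and 0.811 with the replicate block). Of 18 genes for mitochondrial biogenesis and mtDNA maintenance 5 rose and 2 fell (5 and 2 adjusted over the list alone; 8 and 3 with the replicate block). Rrm2b, which supplies deoxynucleotides outside S phase, fell from 14.7 ± 1.05 to 3.71 ± 0.961 CPM (SD, n = 3), and the carrier Tfb2m by 0.77, while Ppargc1b rose by 0.85 and Ssbp1 by 0.58 (camera adjusted p = 0.19). Of 18 mitophagy genes 6 rose and 3 fell (6 and 3 adjusted over the list alone; 6 and 5 with the replicate block), with Pink1 at -0.48, Rhot1 at 0.39, and Gabarapl1 at 0.97 and Bnip3 at 0.74. Exons of the last pair overlap other genes over 28.3 and 22.3% of their length, so their counts are uncertain (camera adjusted p = 0.75). Of 26 genes for calcium handling 3 rose and 6 fell (3 and 6 adjusted over the list alone; 7 and 8 with the replicate block), among them the uniporter regulator Micu3 at -0.91, Itpr1 at -0.65 and the carrier Atp2b2 at -0.54 (camera adjusted p = 0.372).

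Of 28 NRF2 targets and antioxidant genes 10 rose and 4 fell (10 and 4 adjusted over the list alone). Besides Hmox1, the mitochondrial peroxidase Prdx3 rose by 0.59 on the log2 scale and the mitochondrial superoxide dismutase Sod2, a carrier, by 0.77, while catalase (Cat) fell by 0.99. The list was not called (camera adjusted p = 0.0876), though it was without shOpa1 replicate 1 (adjusted p = 0.0382), and over all 6 libraries its adjusted p was 0.676 with an estimated correlation. Of 20 genes of the endoplasmic reticulum unfolded protein response 3 rose and 3 fell (3 and 3 adjusted over the list alone; 5 and 5 with the replicate block). Herpud1 rose by 1.25, Xbp1 fell by 0.66, and the carriers Dnajb9 and Sel1l fell by 1.30 and 1.22 (camera adjusted p = 0.951; median 0.04, mean -0.05). Of 15 cytosolic heat shock genes 5 rose and 3 fell (6 and 3 adjusted over the list alone; 8 and 3 with the replicate block), with Hsf1 at 0.39, Hspa4 at 0.33, Hspa4l at -0.62 and the carrier Hspa1a at -0.96, whose counts are uncertain beside its near-identical neighbour Hspa1b (camera adjusted p = 0.314).

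**Figure D4:**
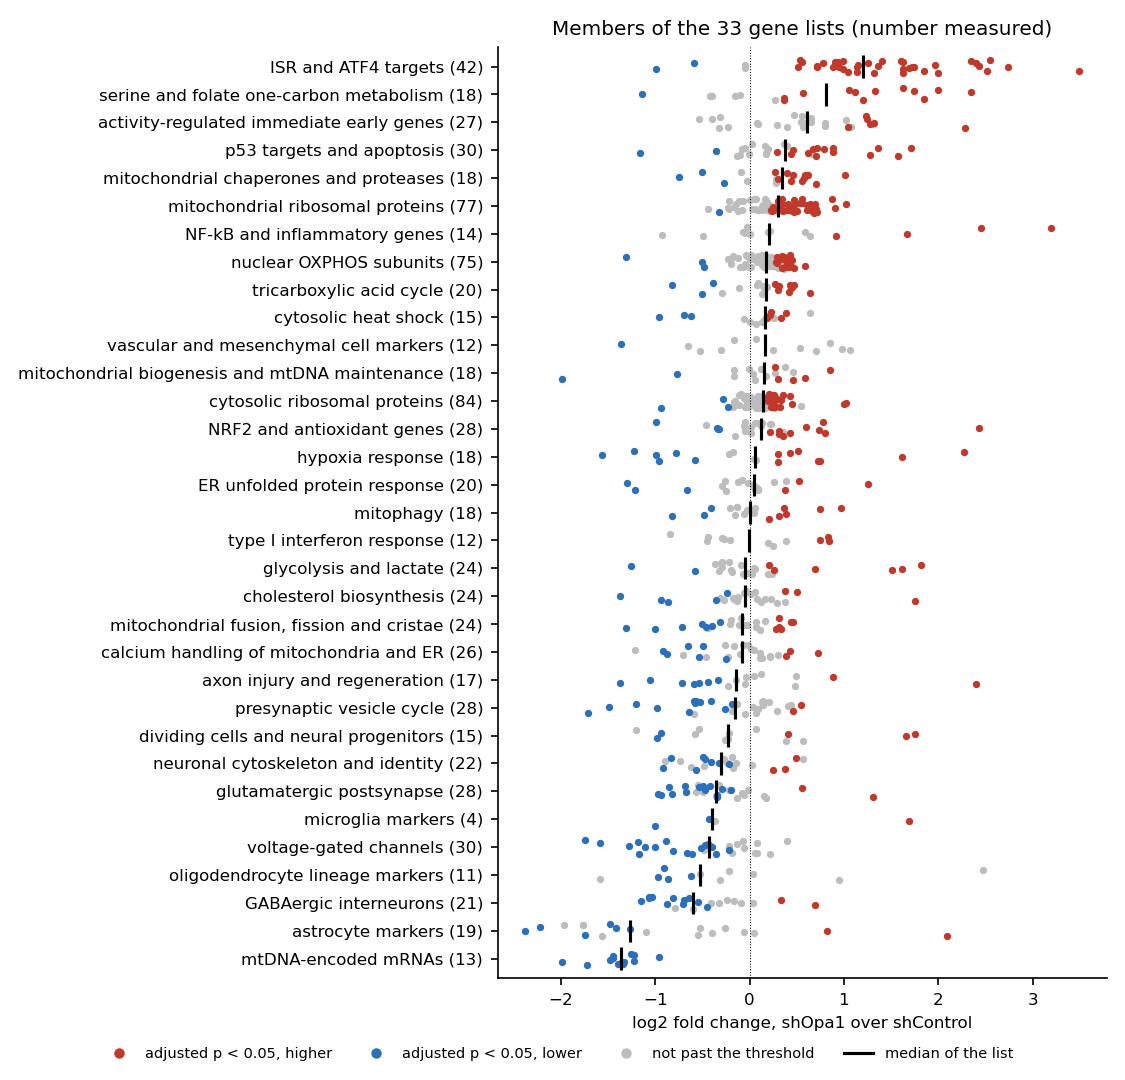
Log2 fold change of shOpa1 over shControl for each measured member of the 33 gene lists, coloured by whether it passed an adjusted p of 0.05, with a black bar at each list's median; lists are ordered by that median and the number measured is in parentheses. ISR and ATF4 targets lie at the top with a median of 1.20 and the mtDNA-encoded mRNAs at the bottom with -1.36.

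Glutamatergic postsynaptic, voltage-gated channel and GABAergic interneuron genes were called lower as lists. Of 28 glutamatergic postsynaptic genes 14 fell and 2 rose (16 and 2 adjusted over the list alone; 21 and 4 with the replicate block). The AMPA receptor subunits Gria1, a carrier, Gria3 and Gria4 fell by 0.85, 0.93 and 0.68 on the log2 scale, and the adhesion protein Nlgn1, a carrier, by 0.97. The list median was -0.35 (-0.42 in pairs 1 and 2, -0.30 in pair 3; camera adjusted p = 0.00349, adjusted p = 0.56 with an estimated correlation). Of 30 voltage-gated channel genes 18 fell and 0 rose (18 and 0 adjusted over the list alone; 22 and 2 with the replicate block), including the carrier Kcna2 at -1.11, Cacna2d1 at -0.89, Kcnh1 at -0.66 and Kcnd3 at -0.43. Their median was -0.43 (-0.45 in pairs 1 and 2, -0.36 in pair 3; camera adjusted p = 0.000671, adjusted p = 0.423 with an estimated correlation). Of the 18, 6 were carriers, and without carriers the median was -0.41. Of 21 genes of GABAergic interneurons 11 fell and 2 rose (12 and 2 adjusted over the list alone), with Calb1 at -0.88 and Dlx5 at -0.70. The vesicular GABA transporter Slc32a1 fell by 0.55, with 24.9% of its exon length shared with other genes. The list median was -0.60 (-0.57 in pairs 1 and 2, -0.73 in pair 3; camera adjusted p = 0.00707, adjusted p = 0.56 with an estimated correlation), and none of the 20 members searched was a carrier.

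The vesicle cycle and neuronal identity lists did not pass camera. Of 28 presynaptic genes 12 fell and 2 rose (12 and 2 adjusted over the list alone; 15 and 9 with the replicate block; camera adjusted p = 0.104). The median was -0.16, and -0.002 without its 6 GAAACTA carriers. The calcium sensor Syt1, a carrier, fell from 1512 to 764 CPM, and Cplx2 and Nrxn3 by 0.64 and 0.58 on the log2 scale. Of 22 genes of neuronal cytoskeleton and identity 8 fell and 3 rose (9 and 3 adjusted over the list alone; 16 and 4 with the replicate block). Cux2 fell by 0.83, Stmn2 by 0.41, and the carriers Elavl3 and Dcx by 0.57 and 0.49. That list's camera adjusted p was 0.0682, and 0.0128 with the replicate block (adjusted p = 0.431 with an estimated correlation and the block). Immediate early genes, which neurons switch on with activity, were higher as a list. Of 27, 6 rose and 0 fell (3 and 0 adjusted over the list alone; 15 and 2 with the replicate block), with Fosb at 2.29, Btg2 at 1.27 and Gadd45b at 1.04. Their median was 0.97 in pairs 1 and 2 and 0.05 in pair 3, and the camera adjusted p was 0.025 (adjusted p = 0.69 with an estimated correlation). The call was lost without shControl replicate 2 (adjusted p = 0.0531), shOpa1 replicate 1 (adjusted p = 0.0812) or shOpa1 replicate 2 (adjusted p = 0.0543). Fry did not call this list either (fry adjusted p = 0.116, and 0.189 with the replicate block).

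Some p53 targets and apoptosis genes rose, and the list that holds both kinds was called. Phlda3 rose from 11.9 ± 0.469 to 39.1 ± 3.93 CPM and Zmat3 from 121 ± 16.9 to 311 ± 26.1 CPM (SD, n = 3). Bax, which opens the outer mitochondrial membrane in apoptosis, rose by 0.62 on the log2 scale, and its antagonist Bcl2 by 0.79. Of 30 genes 14 rose and 2, Perp and Ccng1, fell (15 and 2 adjusted over the list alone), and the median was 0.38 (0.47 in pairs 1 and 2, 0.23 in pair 3; camera adjusted p = 0.00163, adjusted p = 0.423 with an estimated correlation). Of 17 axon injury genes 2 rose and 7 fell (3 and 7 adjusted over the list alone), with Stmn4 at -0.54 and the carriers Klf6, Map3k12 and Sox11 at -1.06, -0.59 and -0.44 (camera adjusted p = 0.314).

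Markers of other cell types moved too. Of 19 astrocyte markers 6 fell and 2 rose (6 and 2 adjusted over the list alone), and with the replicate block 14 fell. Slc1a2, a glutamate transporter and a carrier, fell from 247 to 103 CPM and Slc4a4, also a carrier, from 18.2 to 5.43 CPM. S100b fell too, at a low level, from 0.822 to 0.172 CPM. Ntsr2 rose from 1.505 to 6.42 CPM and Gfap from 0.822 to 1.45 CPM. The median was -1.26 (-1.21 in pairs 1 and 2, -1.19 in pair 3; camera adjusted p = 0.0214, adjusted p = 0.632 with an estimated correlation). Without GAAACTA carriers it was -0.54 and the list was not called (camera adjusted p = 0.125), nor was it after a filter of at least 1 CPM in at least 3 libraries (adjusted p = 0.0912), without shControl replicate 3 (adjusted p = 0.0715) or shOpa1 replicate 1 (adjusted p = 0.0528). Of 11 oligodendrocyte lineage markers 4 fell and 0 rose (4 and 1 adjusted over the list alone; 5 and 2 with the replicate block), with Mog at -0.86 and Cnp at -0.62 (camera adjusted p = 0.314). Only 4 of 19 microglia markers were measured, too few to test, and 1 rose and 2 fell (1 and 2 adjusted over the list alone). Cd68, a lysosomal protein, rose by 1.69, Aif1 fell by 1.00, and Laptm5 stood at -0.37 (adjusted p = 0.37). Of 12 vascular and mesenchymal markers 1, Kdr, fell (1 adjusted over the list alone; camera adjusted p = 0.855), a call lost without shOpa1 replicate 2 (adjusted p = 0.0604). Of 15 genes of dividing cells and progenitors 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.855), with Sox2 at -0.98 and Pcna at 0.41. The medians of these last lists, 0.16 and -0.23, had the opposite sign to the direction camera gave.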

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

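Fits with replicate 3 as a second batch, with pairs 1 and 2 alone, without carriers of the 3' UTR sequence and with estimated correlations beside the block were chosen after the data were seen. With the replicate block, the fit called 9851 genes, 4770 higher and 5081 lower, against 6442, 3130 and 3312 without it. Libraries with the same number were alike, and a term for replicate 3 alone already gave most of this gain (9353 genes with edgeR). Opa1 stayed at -4.48 with the block, and 14 gene lists were called instead of 13, the neuronal cytoskeleton and identity list being gained (camera adjusted p = 0.0128). Among genes named by the rule the block took away the call of Nr4a1 (adjusted p = 0.0782) and gave one to Stat2 (adjusted p = 1.46e-05), and it changed no other of these. Outside the rule, mt-Rnr1 and mt-Rnr2 gained a call with it (adjusted p = 0.000117 and 0.00379). Asking for at least a 2-fold change left 1455 genes, 520 higher and 935 lower. Leaving out 1 library gave -4.57 to -4.43 for Opa1, 4589 to 6626 called genes, 2168 to 3168 higher, 2421 to 3458 lower and 11 to 14 lists. A second batch for replicate 3 gave 9353 genes with edgeR and 7935 with DESeq2, pairs 1 and 2 alone 8496, and the genes without carriers 5538 and 12 lists. Estimated correlations removed all camera calls (0 of 13, also 0 with the block), so those calls rest on the preset correlation of 0.01. Fry uses no preset correlation, but it asks whether members change at all, not whether they change more than other genes. It called 16 lists by direction and 31 in its mixed form, which leaves direction aside. With so many genes called, a fry call sets a list little apart from other genes. Among the 16 were all camera calls but the nuclear OXPHOS, immediate early and cytosolic ribosomal lists. Of 2426 alternative values for named genes, 0 reversed and 40 lost the call, among them values of Nr4a1, Kdr, Ddx58, Bst2, Ptgs2 and Icam1. Without scaling factors the median of all genes moved from -0.01 to 0.11 on the log2 scale, which turned the sign of uncalled lists such as fusion, fission and cristae, but of none that was called. In simulated data 65.5% of 2-fold changes were found, with 200 of 16562 genes changed. In the real data 38.9% of genes were called, so that share need not hold here. Smaller changes and genes with few counts can be missed. The cause of the shift in replicate 3 was not tested.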

Other observations

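The tests on the mitochondrial mRNAs and the regroupings of libraries were chosen only after the results were seen. Some genes that license DNA replication rose, although the list of dividing cells and progenitors was not called. The helicase subunits Mcm2 and Mcm5 rose from 4.75 to 15.0 and from 2.58 to 8.75 CPM, and Pcna by 0.41 on the log2 scale. Chosen after their values were seen, Mcm6 rose from 12.4 to 36.0 CPM and Mcm4 by 1.18. Likewise the licensing factor Cdt1 rose by 2.30 and the chromatin assembly factor Chaf1b by 2.37. Mcm7 stood at 0.03 and Mcm3 at 0.39, neither past the test. Top2a and the GAAACTA carrier Cdk1, which act in mitosis, had log2 fold changes of -1.20 and -0.57 that did not pass, and no list of replication genes was tested.

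Sugar and sterol genes moved apart within their lists. Of 24 genes of glycolysis and lactate 6 rose and 2 fell (5 and 2 adjusted over the list alone; 8 and 10 with the replicate block). The glucose transporter Slc2a1 rose from 7.06 to 21.6 CPM and the lactate transporters Slc16a3 and Slc16a1 by 1.81 and 0.69, while Slc16a7, a GAAACTA carrier, fell by 1.25 (camera adjusted p = 0.855; median -0.04, mean 0.10). Of 18 hypoxia genes 8 rose, such as Vegfa at 0.73, and 6 fell, such as Ndrg1 at -1.23 and Ddit4 at -0.99 (8 and 6 adjusted over the list alone; camera adjusted p = 0.849). In cholesterol biosynthesis 5 of 24 fell and 3 rose (5 and 3 adjusted over the list alone; 11 and 8 with the replicate block). Hmgcs1 fell from 1163 to 449 CPM, the carrier Stard4 fell by 0.94, and Idi1 rose by 0.37 (camera adjusted p = 0.783). Of 14 NF-kB and inflammatory genes 4 rose and 0 fell (3 and 0 adjusted over the list alone; 7 and 1 with the replicate block), with Il1b at 2.45 and Lif at 1.67, both with group means under 1 CPM (camera adjusted p = 0.105, and 0.527 with an estimated correlation; 0.0411 in pairs 1 and 2 alone). Of 12 interferon genes 3 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.653; median -0.01, mean 0.06).

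The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Every other split puts libraries of both groups on each side, which shrinks the difference and widens the spread within a side, so its values are not those of an experiment without a change. The real split gave the largest value in 1 of 10 for Opa1 (4.48 in size against at most 0.93 in another), for the genes called by edgeR (6442 against 0), for the higher genes (3130 against 0) and for the lower genes (3312 against 0). At an unadjusted p under 0.05 the real split gave 7993 genes and another at most 939. For list calls by camera 2 of 10 splits reached 13, the real one and the one that puts shControl replicates 1 and 3 with shOpa1 replicate 3, so that both libraries numbered 3 stand on 1 side. The 3 other splits that part all 3 pairs called 5 to 12 lists, and these too mix the groups. For the real groups 14 lists were called with the replicate block and 16 in pairs 1 and 2 alone.

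Silencing of other genes through the seed of the hairpin against Opa1 could account for part of the fall, but the hairpin sequences are not in the labels or files, so whether a guide pairs with GAAACTA is not known. Among 16220 7-base sequences GAAACTA had the lowest t, -24.6, where 100 permutations reached -4.99, and its reverse complement had a t of 0.30. It lies in the Opa1 mRNA, as 29.2% of the sequences tested do, so that alone says little. Single sites followed by an A had a median of -0.51 against -0.35 for the others (two-sided permutation test of medians, p = 0.0014). Most of the genes that fell at least 2-fold lack the full sequence, as 36.3% carry it, and 72.9% carry either 6-base part of it against 47.9% of the other genes searched, while transcript length and GC content do not account for the fall, as 89.5% of 759 such genes stayed at or below -1 after that trend was removed. Since Mfn2, Immt, Yme1l1 and Ndufs8 carry the sequence and fell, loss of Opa1 and loss of these could both lie behind any later change, including that of the stress response, and no second hairpin or rescue in these data can part them.

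For the genes that rose, silencing by the control hairpin was weighed and cannot be told. The most shifted sequence, GAAGAGC, reached a t of 6.77 against 5.46 at most in permutations. The sequences ranked 2 and 3, AAGAGCA and AGAGCAC, overlap it and reached 6.65 and 5.68, and their carriage by group was not counted. GAAGAGC was carried by 16.8% of the genes that rose at least 2-fold and by 13.7% of the other genes searched (two-sided Fisher's exact test, p = 0.0896). Genes that fell at least 2-fold carried it in 15.9%, those called lower by less in 15.0%, those called higher by less in 15.4% and those not called in 12.6%. Carriage was thus much alike in genes that rose and fell, but these shares were not adjusted for 3' UTR length. With the trend on length and base composition removed, GAAGAGC carriers stood 0.107 higher on the log2 scale. A large mean shift of its carriers was thus not seen, and a contribution through it or the overlapping sequences stays open. The rise might also follow from loss of Opa1 or of the carriers of GAAACTA.

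The fall of the mitochondrial mRNAs is not made by scaling, since the highest of their medians over 4 scalings was -1.23. A fall of both genomes' genes does not account for it either, as the nuclear OXPHOS subunits had a median of 0.17. Nor did all mitochondrial transcripts fall alike: mt-Rnr1 and mt-Rnr2 stood at 0.31 and 0.21 (edgeR adjusted p = 0.0812 and 0.426; 0.000117 and 0.00379 with the replicate block). These rRNAs are read here through poly(A) selection, so their levels are a weak guide. Less stable mRNA or a change in polyadenylation could each give this pattern. Less mitochondrial DNA could lower the mRNAs, but would not by itself spare the rRNAs, as far as these can be read here. None of these was measured.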
